A study of Mus musculus with 56 samples.

How the data were processed

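The series holds 56 mouse samples. Values were used from 26 bulk RNA-seq libraries of liver tumours and healthy liver and from 15 T cell receptor (TCR) libraries of liver tumours. The other 15 samples, droplet gene expression libraries, were not analysed here.

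For the bulk libraries the authors deposited 1 table of TPM, transcripts scaled to 1000000 per library, named as such by its title. The deposited TPM values of each of the 18 libraries without a male label add up to 1000000 within 0.1, and those of the 8 male libraries miss it by -3.8 to 256.3. TopHat2, featureCounts, DESeq2 and the mouse build mm10 are listed for these samples, per the submitters' processing notes. Their roles and versions are not given in the sources used here, nor is the gene annotation or a filter. TPM keeps no read depth, so the depth of each bulk library is unknown and no counting interval is given for a gene. Of the 24063 genes in the table, 27 had names turned into dates by a spreadsheet and 2 shared a name, and these were left out, leaving 24034. Of these, 23020 matched a current mouse symbol, 854 an older symbol and 160 none. The date-like names held at most 0.224% of a library's TPM.

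For the TCR libraries the authors deposited tables of assembled receptor contigs, with the counts of UMIs and reads behind each contig. Cell Ranger, Seurat and mm10 are listed, per the submitters' processing notes, with versions not given in the sources used here. Per the labels' protocols, tumour cells and CD45 positive immune cells were mixed again in equal numbers before loading, so the share of immune cells was set by hand. A T cell was a barcode called a cell with at least 1 productive, high-confidence TRB contig, and the contig with the most UMIs was kept. Barcodes with 2 or more such contigs, up to 7.513% of the T cells of a library, were kept, and leaving out those with 2 or more TRB or 3 or more TRA as possible doublets was an alternative. A clonotype was 1 combination of V gene, J gene and CDR3. A library held 49 to 1282 T cells, with a median of 6 to 14 UMIs in the TRB contig. Intervals on shares are 95% Wilson intervals and cover counting error only.

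Groups came from the titles and genotype labels. Bulk TPM values were tested on the log2(TPM + 1) scale with limma 3.58.1 (trend and robust spread) in R 4.3.3, so a fold change understates the change of genes with low TPM. Genes needed at least 1 TPM in at least 4 libraries of the fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Healthy liver was compared with the equal-weight mean of the 4 tumour groups over all 26 libraries. The antigen comparisons, the male comparisons and their interaction were fitted together on the 20 tumour libraries. Where a text value is a tumour mean over all groups, it is the mean of the 4 group means.

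The 34 gene lists were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. TCR measures were compared per animal with two-sided exact permutation tests, with labels permuted within NICD and sgp53 or within luc and lucOS. The pair of libraries from 1 animal, female lucOS sgp53 replicates 3 and 4, was averaged. These 10 TCR tests were adjusted together, their dependence on the settings was judged by the unadjusted p, and V gene usage was adjusted over the 20 TRBV entries with a mean share of at least 1%. For the expanded share, every library was thinned to 151 T cells in 200 draws, and 2 libraries under 100 T cells were left out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

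Group assignments, tests, gene lists, most alternative settings and the naming rule were fixed before the data were examined. The naming rule took, per comparison, up to 5 genes with the largest rise and 5 with the largest fall among called genes of at least 5 TPM whose groups did not overlap. It left out predicted genes, pseudogenes and receptor variable segments. It added up to 2 called members of each gene list past its threshold, and a fixed set of 18 genes in the comparisons they bear on. Which of those genes bear on which comparison was set after their values had been seen. Where under 5 genes were called, the 5 with the smallest p were named. Of the 18, Cd3e, Cd8a, Gzmb, Ifng and Pdcd1 did not reach 1 TPM in 4 libraries and were not tested. 1 gene chosen by the rule is not reported here. A list of 15 lung epithelial genes, the regroupings of the samples and the settings named as such in the account of how the results depend on the processing were chosen after the data were seen.

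On simulated TPM with 100 genes changed by 1 log2 unit, the tumour against healthy step recovered 93% of them and the antigen step in males 66%. The antigen step in tumours with no sex in the title recovered 82%. The male steps recovered 73% in luc and 78% in lucOS tumours, and the interaction step 60%. The changed genes were drawn only from genes of higher TPM, and genes varied independently. These shares thus do not hold for genes of low TPM. The TCR test, simulated 200 times over 12 animals, called 4.5% of cases with no difference and 84.5% of cases with a difference of 20 points at an SD of 10. The test of the expanded share for lucOS had only 6 and 4 animals and an SD of 13.6 in lucOS, a setting that was not simulated.

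Alternatives were other pseudocounts, filters, scalings, limma settings and sets of libraries for bulk values, each library left out in turn, and other clonotype definitions, UMI minimums and sets of T cells for TCR values. Tests that need read counts were not run, because whole reads cannot be recovered from TPM.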

Results

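Mouse liver tumours were profiled by bulk RNA-seq and by TCR sequencing to compare tumours that carry MYC and NICD, the active intracellular part of NOTCH1, with healthy liver, between antigen constructs and between sexes. Tumours arose after hydrodynamic tail vein injection, which delivers plasmid DNA to hepatocytes. The construct luc carries luciferase, and lucOS carries luciferase joined to model T cell antigens. Bulk libraries came from 6 healthy livers, 6 luc and 6 lucOS tumours with no sex in the title, and 4 luc and 4 lucOS tumours whose titles say males. All 20 tumours are labelled NICD. TCR libraries came from 3 female animals each of luc NICD, lucOS NICD, luc sgp53 and lucOS sgp53, and from 2 male lucOS NICD animals. The label sgp53 names a guide RNA against the tumour suppressor p53, in place of NICD. Bulk libraries listed 16921 to 19172 genes above 0 TPM.

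Tumours held far more Notch1 RNA than healthy liver and had lost most of the liver's own programme. Notch1 averaged 621.5 TPM in tumours against 5.93 ± 2.66 TPM (SD, n = 6) in healthy liver, a log2 fold change of 6.51 ± 0.21 (SE, limma adjusted p = 3.08e-19). TPM per gene cannot tell RNA of the NICD construct from that of the mouse's own gene. Nrarp, a NOTCH target that feeds back on the pathway, rose by 9.41 on the log2 scale, Hes1 by 2.34 and the biliary factor Sox9 by 2.53. Of 17 tested NOTCH pathway genes, 15 were higher and 1 lower, also when adjusted over the list alone, with a median log2 fold change of 2.87. The NOTCH list did not pass camera (adjusted p = 0.0901). Myc rose from 4.90 ± 2.08 TPM (SD, n = 6) to 20.2 TPM, a log2 fold change of 1.84. Whether RNA of the MYC construct is counted as Myc cannot be told from TPM per gene either.

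All 18 proliferation genes rose, with a median of 4.77, among them Cdc20, which drives exit from mitosis (6.11), and the topoisomerase Top2a (5.93). All 20 MYC target and ribosome biogenesis genes rose, with a median of 2.65, among them Cad of pyrimidine synthesis (3.94) and the nucleolar gene Npm1 (3.50). The fetal growth genes Igf2 (9.66) and H19 (9.33) rose, as did the smooth muscle actin gene Acta2 (9.42). Akr1cl, listed at 0 in all 6 healthy livers, averaged 925.7 TPM in tumours. The fetal liver gene Afp did not pass (-0.43, adjusted p = 0.547), with 3.29 ± 1.21 TPM in healthy liver, 23.8 ± 35.9 in luc and 0.704 ± 0.564 in lucOS tumours (SD, n = 6 each), and 7.30 ± 8.11 in luc and 0.716 ± 0.242 in lucOS males (SD, n = 4 each). With quantile normalization it was lower (-1.62, adjusted p = 0.0283).

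All 18 secreted hepatocyte proteins fell, with a median of -5.27, among them albumin, Alb (-6.37), and Apoa2 (-6.96). All 17 bile acid and xenobiotic genes fell (median -5.79), among them Cyp2c29 (-8.04) and Ugt2b1 (-7.37). Periportal genes such as Cyp2f2 (-7.71) and the urea cycle gene Otc (-6.80) fell in 13 of 14 cases, and 11 of 16 pericentral and WNT target genes, such as Cyp1a2 (-8.10) and Cyp2e1 (-7.56), fell while 2 rose. Of the male-biased liver genes 14 of 15 fell, led by Mup3 (-10.60) and the transporter Slco1a1 (-6.43), and of the female-biased genes 17 of 18 fell, led by Cyp2a4 (-9.06) and Cyp2b9 (-7.76). Sex was not balanced here, since healthy livers held 50.8 to 103.6 TPM of Xist, made in females, and 0 of the Y-linked Ddx3y, while the tumour mean includes males. In tumours with no sex in the title the leading genes were low too. Mup3 averaged 7458 TPM in healthy liver, 1.97 in luc and 14.2 in lucOS tumours, and Cyp2a4 1072, 1.48 and 5.16. The fatty acid binding protein gene Fabp1 (-9.17), Hamp2 (-9.15) and Cyp2c69 (-9.05) were among the largest falls.

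Many MHC class I and interferon genes were lower in tumours, while MHC class II genes were not. Of 16 MHC class I genes 9 fell and 2 rose, and B2m, the shared class I light chain, fell from 2741 ± 521 TPM (SD, n = 6) to 461.0 TPM (-2.68), as did H2-T23 (-3.41). Of 15 type I interferon genes 9 fell and 2 rose, the falls including Irf7 (-2.21) and Ifit3 (-1.89), and of 15 interferon gamma genes 7 fell and 2 rose, the falls including Iigp1 (-4.43) and Igtp (-2.34). Of 10 MHC class II genes 7 were higher and 0 lower (median 0.90, and 0.056 with quantile normalization), with H2-Ab1 at 23.8 ± 7.69 TPM in healthy liver and 44.2 to 315.5 TPM in the means of the tumour groups, and the list did not pass camera (adjusted p = 0.679). Of 9 markers of Kupffer cells, the resident macrophages of the liver, 6 fell and 2 rose, the falls including Clec4f (-3.89) and Nr1h3 (-3.32). In all, limma called 13986 of 15767 genes, 11328 higher and 2658 lower, and camera called 12 lists. Healthy livers and tumours have animal numbers of separate series, so tumour and series cannot be told apart. With an estimated correlation the pericentral list held (adjusted p = 0.0461), and the other 11 had adjusted p of 0.0605 to 0.638. The median gene was higher by 1.03 on the log2 scale. Scaling each library by its median ratio moved that median to 0.083 and gave 6840 higher and 6352 lower genes, and quantile normalization gave 6772 and 5953, so directions near that shift depend on the scaling.

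**Figure D1:**
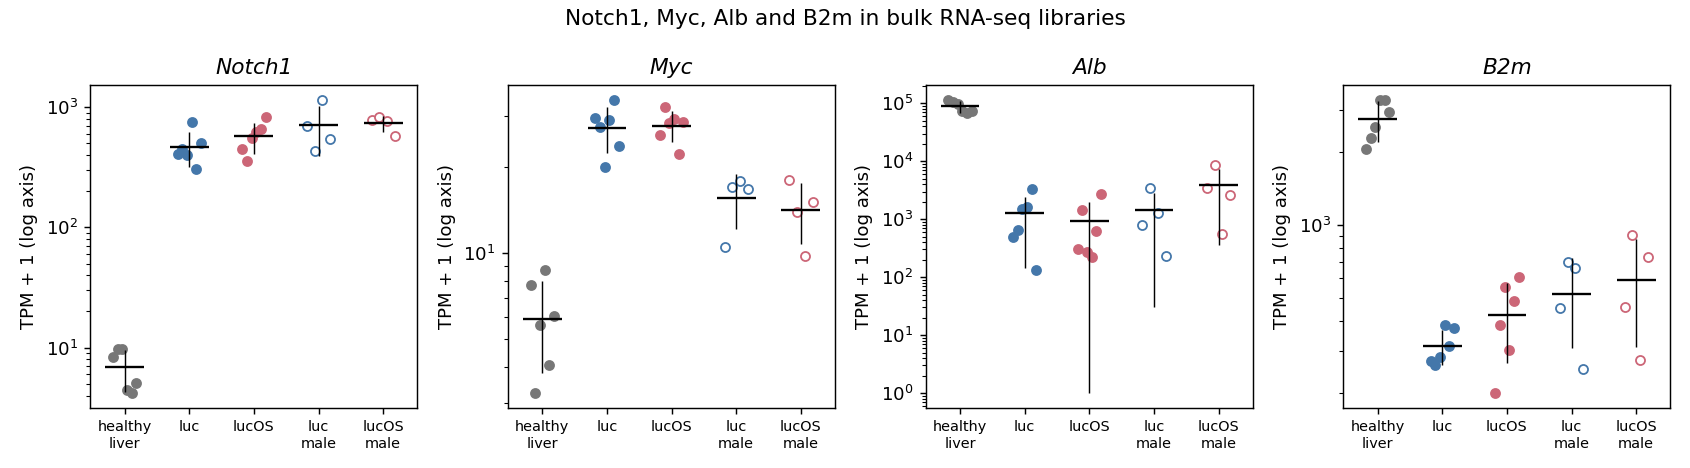
TPM + 1 of Notch1, Myc, Alb and B2m on log axes in each bulk library of 5 groups, with filled points for groups with no sex in the title and open points for male groups. Lines give the mean and bars the SD (drawn to no less than 1) over 6 or 4 libraries, and every tumour lies above every healthy liver in Notch1 and Myc and below it in Alb and B2m.

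The male label was compared with tumours that give no sex, to see how tumours differ between sexes. Xist, which silences the X chromosome in females, was 136 ± 33.5 TPM in luc and 123 ± 21.7 in lucOS tumours with no sex in the title (SD, n = 6 each), and 0.841 ± 0.0248 and 0.452 ± 0.369 in the male groups (SD, n = 4 each). The Y-linked gene Ddx3y was 34.0 ± 4.80 and 35.1 ± 16.9 TPM in the male groups and at most 0.164 TPM in the other tumours. All 4 Y-linked genes tested rose in both constructs (camera adjusted p = 0.000571 and 0.00162 with an estimated correlation). Genes of B cells leaned higher in male tumours of both constructs. Cd79a, part of the B cell receptor, was 7.53 ± 1.81 TPM in luc males against 0.229 ± 0.158 (log2 fold change 2.78, limma adjusted p = 1.03e-07). It was 7.70 ± 3.38 TPM in lucOS males against 0.497 ± 0.291 (log2 fold change 2.49, limma adjusted p = 3.44e-07).

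Of 10 B cell and plasma cell genes 6 were higher in luc males (median 1.15) and 8 in lucOS males (median 1.27), and adjusted over the list alone 7 and 9. Among them were Cd79b in luc (1.97) and the antibody joining chain Jchain in lucOS (2.23, and 0.94 without lucOS male replicate 2). Of 6 genes of lymphoid chemokines and homing 3 rose in each construct, among them Ccr7 (2.04 in luc, 1.91 in lucOS). MHC class II genes rose in 4 of 10 cases in luc (H2-Ab1, 2.12; H2-Ob, 1.18) and in 8 of 10 in lucOS (Cd74, 2.46; H2-Eb1, 2.22). MHC class I genes rose in 7 of 16 cases in luc (H2-Q7, 2.16; H2-Q4, 1.80) and in 3 of 16 in lucOS (H2-T23, 1.64; Tapbp, 1.02). Adjusted over the list alone, 7 and 10 of the class II genes and 11 and 6 of the class I genes rose. These 4 lists passed camera in both constructs, with adjusted p = 0.605 in luc and of 0.705 to 0.717 in lucOS with an estimated correlation.

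Myc was lower in male tumours, and lists tied to growth leaned the same way with few members called in luc. Myc fell by 0.83 on the log2 scale in luc and by 1.00 in lucOS tumours, and Nme1, a MYC target, fell by 0.89 and 0.90. The values of Myc may include RNA of the MYC construct. The MYC target list had medians of -0.27 and -0.45 with 2 and 11 of 20 genes lower (Nop58 in luc, -0.57; Odc1 in lucOS, -0.84). Proliferation had medians of -0.27 and -0.67 with 2 and 7 of 18 lower (Tyms in luc, -0.81; Ccna2 in luc, -0.75; Rrm2 in lucOS, -1.20; Birc5 in lucOS, -1.10). Of 14 respiratory chain genes 8 fell in luc, and 2 fell and 1 rose in lucOS, the falls including Cox5a (-0.96, -0.86), Cox7a1 in luc (-1.15) and Ndufa1 in lucOS (-0.54). With an estimated correlation these lists had adjusted p of 0.605 to 0.741. Notch1 did not pass in either construct (adjusted p = 0.170 and 0.285).

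T cell genes rose in 2 of 8 cases in each construct (Cd2, 1.54 and 1.70; Thy1 in luc, 1.27; Cd4 in lucOS, 0.91). Cd2 and Cd4 are no clear measure of T cells here, since the T cell gene Cd3e lay lower. In luc males Cd3e was 0.252 ± 0.140 TPM and Cd2 2.36 ± 0.266 (SD, n = 4 each). In lucOS males Cd3e was 1.22 ± 0.952 TPM and Cd4 3.41 ± 1.51 (SD, n = 4 each). Endothelial genes rose in 2 and 6 of 12 cases (Tek and Kdr in luc, 2.77 and 0.87; Plvap and Ptprb in lucOS, 1.18 and 0.97). Type I interferon genes rose in 1 of 15 each (Oasl1 in luc, 1.38; Ifit2 in lucOS, 0.66). In luc males, 3 of 10 monocyte and neutrophil genes rose (Chil3, 2.52, and 1.58 without luc male replicate 2; Il1b, 1.67). So did 3 of 13 hypoxia genes (Ndrg1, 1.81; Vegfa, 1.06) and 7 of 12 immediate early and heat shock genes (Fosb, 1.77; Jun, 1.40), of which 1 more fell. Of 12 p53 targets 3 fell (Zmat3, -1.35; Ccng1, -1.29; -0.89 and -0.99 without luc male replicate 3). In lucOS males, 6 of 14 macrophage genes rose (Apoe, 1.61; Csf1r, 1.58), as did 5 of 16 bile acid genes (Cyp2c29, 2.33; Abcb11, 1.88) and 6 of 14 pericentral genes (Cyp27a1, 1.83; Cyp1a2, 1.85). Apoe is no clear sign of macrophages here, since healthy liver held 31310 ± 3704 TPM of it (SD, n = 6) and lucOS males 4164 ± 1925 (SD, n = 4). The complement gene C3 was the 1 of 18 secreted hepatocyte proteins that rose (2.69), and 3 of 14 interferon gamma genes rose (Irf8, 1.20; Gbp5, 1.09). These lists had adjusted p of 0.605 to 0.717 with an estimated correlation, and the test of the difference between constructs is the interaction of antigen and male label. Foxp3, the regulatory T cell factor, was at the threshold in luc males (-0.41, adjusted p = 0.0480). At 6.7 ± 0.81 TPM in luc tumours, where the T cell gene Cd3e was 0.042 ± 0.072 (SD, n = 6), Foxp3 is no measure of regulatory T cells here. It lost that call without any 1 of the luc male libraries or of luc replicates 1 to 5, and under 4 other settings (adjusted p of 0.0501 to 0.165). Its adjusted p was 0.0550 in lucOS, where quantile normalization gave -0.66 (adjusted p = 0.00396). Thy1 in luc (adjusted p = 0.0411) likewise lost its call without any 1 of the luc male libraries or of luc replicates 1, 2, 3 and 5, and under 4 other settings (adjusted p of 0.0504 to 0.103). Sox9, Hes1, Cd274, Cxcl9 and B2m did not pass in either construct, but Sox9 in luc males passed with array weights (1.51, adjusted p = 0.0302) and without luc male replicate 4 (2.37, adjusted p = 0.00623). Of the called genes tested across settings, 15 of 39 in luc and 15 of 39 in lucOS lost the call when 1 library was left out, and 6 and 9 did under other settings. With only the groups compared in the fit, these included Chil3, Zmat3 and Ccng1 in luc and Cd74, H2-Eb1, Jchain, Cyp2c29 and Cd4 in lucOS (adjusted p of 0.0516 to 0.104), and with array weights Ccng1 in luc was -0.59 and Cox7a1 -0.68 (adjusted p = 0.244 and 0.115). Without luc male replicate 3, 14 were lost, H2-Ab1, Foxp3 and Vegfa among them (adjusted p of 0.0542 to 0.165). Without lucOS male replicate 4 or 2, 14 or 13 were lost, Cd74, Csf1r and C3 among them (adjusted p of 0.0515 to 0.186). Each other luc or lucOS library ended 1 to 9 calls, except lucOS male replicate 3, which ended none.

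Male tumours also held transcripts of lung epithelium and less of several ribosomal pseudogenes. Sftpc, a surfactant protein of the lung, was 13.6 ± 6.96 and 19.9 ± 8.06 TPM in luc and lucOS males (SD, n = 4 each) and at most 0.323 TPM in the other tumours. Of 9 tested lung genes 6 were higher in luc and 5 in lucOS males, among them Sftpb (0.90, 1.16) and Napsa (1.52, 1.44). The counts include Sftpa1 in both constructs and Cyp2f2 in luc (2.09), which are no sign of lung here, since healthy liver held more of them than male tumours did, at 1.90 ± 0.486 and 963 ± 181 TPM (SD, n = 6). Scgb1a1 was 3.18 ± 1.51 and 5.97 ± 6.43 TPM in luc and lucOS males (SD, n = 4 each) and was listed at 0 in all 6 lucOS tumours with no sex in the title. This list of 15 lung genes was written after most had been looked at, and healthy liver had 3 of them above 1 TPM. The 7 ribosomal pseudogenes tested were lower in both constructs, with medians of -1.58 and -1.82. Their median gap to their 6 parent genes was 1.07 and 1.21, but summed over all 7 they held 24.17% of their parents' TPM in luc and 22.46% in luc males, and 24.25% and 22.67% in lucOS. Reads of such copies can be split with their parents by the authors' counting, which leaves these values and that of Rpl32l (-3.47, -3.82) uncertain. MicroRNA genes held 11.4% ± 2.82 and 10.0% ± 1.42 of TPM in male tumours (SD, n = 4 each) and 7.40% ± 0.853 and 7.58% ± 0.598 in the others (SD, n = 6 each). All such values are TPM of the genes in bulk RNA-seq, and mature microRNAs were not measured. Mir703 was lower in both constructs (-2.97, -2.94), Mir6236 in luc (-3.35) and Mir3077 in lucOS (-3.24). The means of Mir6236 and Mir3077 lay lower in the other construct too. Mir6236 was 997.9 ± 172.2 TPM in lucOS males (SD, n = 4) against 7660 ± 4644 in lucOS (SD, n = 6). Mir3077 was 5.3 ± 2.1 TPM in luc males (SD, n = 4) against 37.8 ± 12.6 in luc (SD, n = 6).

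In luc tumours limma called 2613 of 15453 genes, 1382 higher and 1231 lower in males, and in lucOS tumours 3778, 2342 higher and 1436 lower. Among them were the Y-linked genes Eif2s3y (87.2 ± 17.1 and 91.3 ± 22.1 TPM in the male groups), Kdm5d (3.45, 3.89) and Uty (3.18, 3.34). Tsix, antisense to Xist, fell by 4.27 and 4.25, and its reads cannot be told from those of Xist without strand. Both comparisons, which share no libraries, called 670 genes higher, 759 lower and 3 in opposite directions, where independent lists would share 209.5 and 114.4. The log2 fold changes correlated across genes (r = 0.526), and genes are not independent replicates. With quantile normalization the split was 1097 higher and 1573 lower in luc and 1299 and 2220 in lucOS, and the median gene in lucOS moved from 0.13 to -0.02. It was 1489 and 2085 in lucOS with median ratio scaling, and in luc 2109 and 1221 with array weights and 1795 and 957 without microRNA genes. All 8 male tumours have animal numbers of 1 series that no other tumour has, so sex and series cannot be told apart. Their deposited TPM values miss a sum of 1000000 by 3.8 to 256.3, while those of each other bulk library reach it within 0.1, so a separate processing cannot be told apart from sex either. Without luc male replicate 3 the luc count was 1488, and without lucOS male replicate 4 or 2 the lucOS count was 1863 or 2137.

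**Figure D2:**
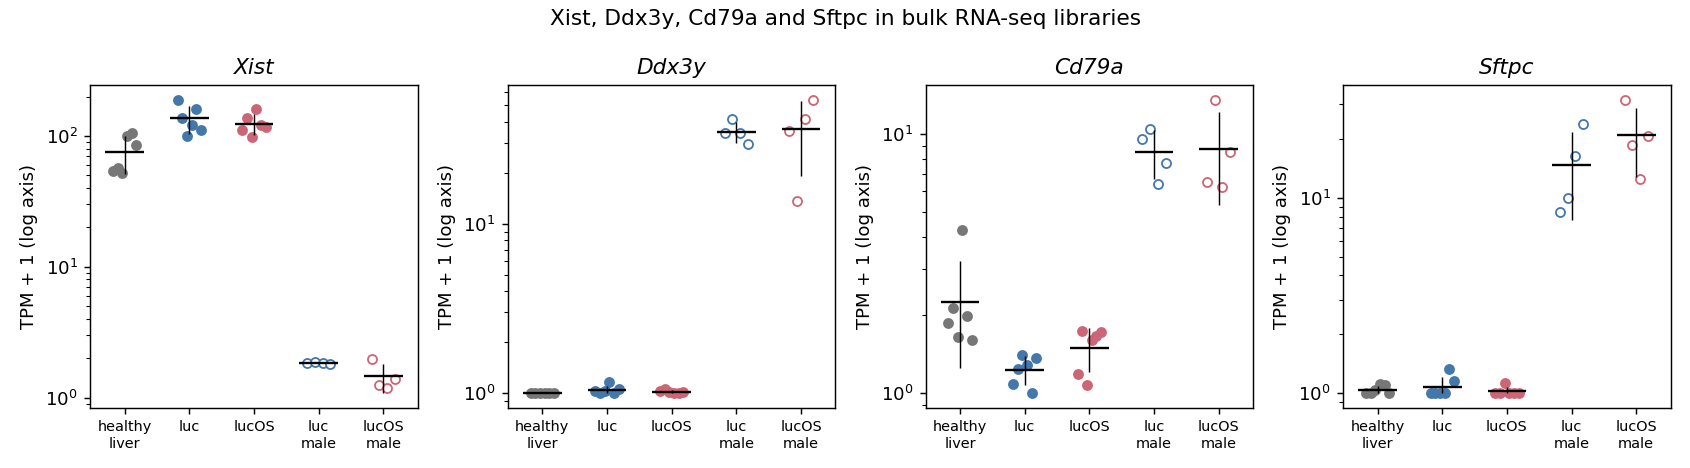
TPM + 1 of Xist, Ddx3y, Cd79a and Sftpc on log axes in each bulk library of 5 groups, with filled points for groups with no sex in the title and open points for male groups. Lines give the mean and bars the SD (drawn to no less than 1) over 6 or 4 libraries, and Ddx3y, Cd79a and Sftpc lie higher and Xist lower in all 8 male tumours than in each of the other 12 tumours.

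The antigen construct was compared with luc to see how antigen alters these tumours. In tumours with no sex in the title, MHC class II and interferon genes leaned higher with lucOS as groups, with no single gene called, and MHC class I genes did not pass (camera adjusted p = 0.0900). All 14 interferon gamma genes had positive fold changes (median 0.46), and so did all 10 MHC class II genes (median 0.49). The lists for type I interferon (median 0.44), cytotoxic effectors (0.43), proliferation (0.18), MYC targets (0.13) and the respiratory chain (0.11) passed camera as higher. Secreted hepatocyte proteins (-0.43) and stellate cell and fibroblast markers (-0.15) passed as lower. All 9 lists had an adjusted p of 0.885 with an estimated correlation. With the animal number series, of which there are 2 in each group, as a term, limma called 0 genes (416 at an unadjusted p under 0.05) and camera called these 9 lists again. The T cell chemokine Cxcl9 was 2.62 ± 2.75 TPM with lucOS and 0.220 ± 0.173 with luc (SD, n = 6 each, adjusted p = 0.997). Limma called 0 of 15453 genes, also over the lists alone, and 385 had an unadjusted p under 0.05, which is 2.49%. Without lucOS replicate 1 it called 1 gene. The smallest p belonged to Anxa11 (-0.36), Mir219c (listed at 0 in all 6 lucOS tumours), Mir7051 (0.78), Mlph (-0.64) and Snai1 (-0.66). Notch1, Myc, Cd4, Foxp3, Cd274 and B2m had log2 fold changes of -0.21 to 0.35. The T cell genes Cd3e, Cd8a, Gzmb, Ifng and Pdcd1 were too low to be tested, and their means lay higher with lucOS in both kinds of tumour. Cd8a was 0.113 ± 0.114 TPM with luc and 0.532 ± 0.457 with lucOS (SD, n = 6 each), and 0.210 ± 0.0829 and 2.16 ± 2.45 in males (SD, n = 4 each).

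In male tumours the genes that rose most with lucOS were the adhesion receptor Adgrd1, at 37.3 ± 14.8 TPM against 2.99 ± 1.33 (SD, n = 4 each, log2 fold change 3.25, limma adjusted p = 0.0181), and the matrix metalloproteinase Mmp17 (3.19). Luc tumours with no sex in the title had 21.0 ± 19.8 TPM of Adgrd1 (SD, n = 6). Ube2u (2.28), the angiotensin receptor family gene Mas1 (2.05) and the neuropeptide receptor Adcyap1r1 (1.93) rose as well. The microRNA gene Mir210, tied to hypoxia (-2.53), alkaline phosphatase Alpl (-1.91), the laminin gene Lamb1 (-1.48), Nyap1 (-1.47) and Fkbp5, which responds to glucocorticoids (-1.32), fell. Interferon gamma (median 0.77), MHC class II (1.09), macrophage (0.80), p53 target (0.55) and respiratory chain (0.34) genes were higher as lists. Hypoxia (-0.57), proliferation (-0.19), MYC target (-0.10), oncofetal (-0.65) and biliary (-0.22) genes were lower as lists. All 10 lists had an adjusted p of 0.869 with an estimated correlation, and none of their members was called over all genes. Adjusted over the list alone, 10 of 14 respiratory chain genes and 2 of 10 MHC class II genes were higher and 3 of 13 hypoxia genes lower. Notch1, Myc, Cd4, Foxp3, Cd274, Cxcl9 and B2m did not pass.

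Limma called 54 of 15453 genes in males, 40 higher and 14 lower with lucOS, and 2675 had an unadjusted p under 0.05. Each of the 10 named genes lost the call without lucOS male replicate 2 (adjusted p of 0.0676 to 0.161) and without luc male replicate 3 (0.0535 to 0.186). The split was 21 to 28 with median ratio scaling, 33 to 28 with quantile normalization and 35 to 34 with array weights, and the count was 0 with the 8 male libraries alone in the fit. Without lucOS male replicate 2 it was 0, without luc male replicate 3 it was 3, without lucOS male replicate 1 it was 6, without luc male replicate 2 it was 12, without lucOS male replicates 4 and 3 in turn 18 and 114, and without luc male replicate 4 it was 578.

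**Figure D3:**
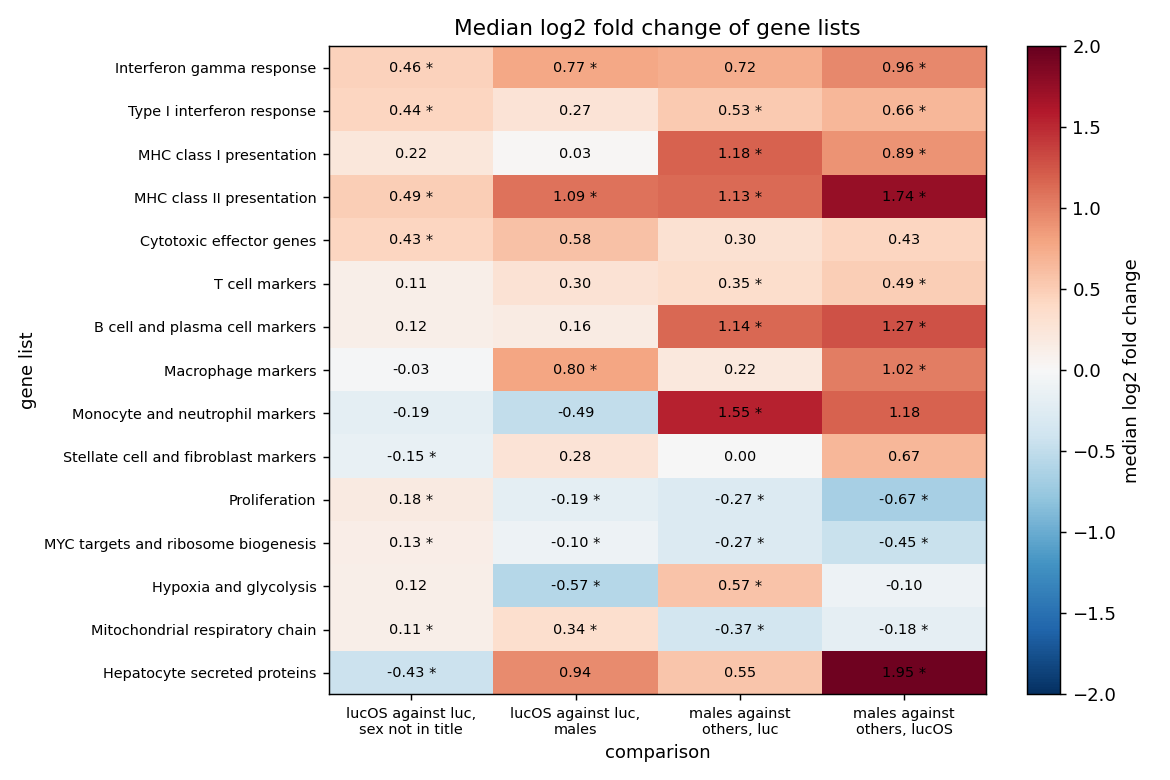
Median log2 fold change (numbers and colours, blue lower and red higher) of 15 gene lists, 1 per line, in 4 comparisons of tumour groups, 1 per column, where * marks an adjusted p under 0.05 by camera with a preset correlation. MHC class II genes lie above 0 in all 4 comparisons and proliferation genes below 0 in 3 of them, and no marked value passes with an estimated correlation.

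The difference of the antigen effect between male and other tumours was tested directly. The change with lucOS lay higher in males than in the other tumours for secreted hepatocyte proteins (median difference 1.37, 18 of 18 genes positive) and macrophage markers (0.71, 14 of 14). It lay lower for hypoxia genes (-0.615, 13 of 13 negative), oncofetal genes (-0.47), proliferation genes (-0.42, 18 of 18) and MYC targets (-0.15). These 6 lists passed camera, with adjusted p of 0.921 to 0.927 with an estimated correlation. Limma called 0 of 15453 genes for the difference, and 1842 had an unadjusted p under 0.05. It called 4 with the healthy livers in the fit and 1 without luc male replicate 4. The smallest p belonged to Tvp23a (0.91), Tcf3 (-0.83), Krt222 (1.34), Mir210 (-3.42) and Ube2u (2.43). Notch1, Myc, Cd4, Foxp3, Cd274, Cxcl9 and B2m had adjusted p of 0.421 to 0.953. Across genes, which are not independent replicates, the antigen fold changes of both kinds of tumour correlated at r = -0.101.

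T cells of lucOS tumours belonged more often to expanded clones. None of the 10 TCR tests passed after adjustment, and the p first given for each is unadjusted. The family of 10 includes the tests of males against females, which had 10 splits each and could not pass. Counting them raises the adjusted p of the tests with a small p, so the value of 0.0625 depends on the make-up of the family. An adjustment without them was not run. After thinning, 37.4% ± 13.6 of T cells in lucOS females (SD, n = 6) and 11.2% ± 8.78 in luc females (SD, n = 4) shared their TRB clonotype with another cell. That is 26.2 points more by two-sided exact permutation (p = 0.025, adjusted p = 0.0625 over 10 tests), with 4 of 6 lucOS animals above every luc animal. Within sgp53 animals the difference was 29.7 points (n = 3 each, exact permutation p = 0.2), and the NICD animals hold only 1 luc animal here. Leaving out any of 8 animals, such as luc NICD replicate 1 (24.7 points), brought the unadjusted exact permutation p to 0.05 to 0.1. The largest clone of a library held 1 to 127 cells, and the highest share was 22.4% (95% interval 17.8 to 27.8) of 268 T cells in lucOS NICD replicate 3.

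Invariant NKT cells, read from TRAV11 joined to TRAJ18, were a smaller share with lucOS. They were 1.48% ± 0.752 of T cells with a TRA in lucOS and 3.14% ± 1.36 in luc females (SD, n = 6 each), a difference of -1.66 points by exact permutation (p = 0.025, adjusted p = 0.0625). All 6 lucOS animals lay below the luc mean. Without luc NICD replicate 3 the difference was -1.24 points, and without lucOS sgp53 replicate 2 it was -1.49 (exact permutation p = 0.05 and 0.065). With at least 3 UMIs in the TRB contig it was -0.912 points (exact permutation p = 0.235), and with the 2 libraries under 100 T cells left out -1.42 points (exact permutation p = 0.05). Without the lucOS sgp53 animal with 2 libraries it was -1.66 (exact permutation p = 0.05).

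TRB clonotypes were shared more often between lucOS animals than between luc animals. Of 1000000 possible pairs of clonotypes from different animals, 29.6 matched in amino acids between lucOS females and 3.52 between luc females, from 58 and 9 matches over 15 pairs of animals each. That is 26.03 more by exact permutation over 6 and 6 animals (p = 0.02, adjusted p = 0.0625). Every luc pair with luc NICD replicate 2 or 3, libraries of 77 and 49 T cells, had 0 matches, which lowers the luc mean. The other luc pairs had 0 to 18.6 matches per 1000000, and lucOS pairs 0 to 93.8. Without luc NICD replicate 1 the difference was 25.5 (exact permutation p = 0.05). The clonotype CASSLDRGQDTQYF with TRBV16 and TRBJ2-5 was in the most animals, 3 lucOS and 3 luc, all sgp53, and 6 clonotypes were in 4 animals each. The 2 libraries of 1 lucOS sgp53 animal shared 59 clonotypes by nucleotides, holding 56.5% of the T cells of replicate 4, against at most 4 in the other 104 pairs of libraries.

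V gene usage was compared as well. TRBV12-1 and TRBV12-2, used by a well-known receptor against the ovalbumin peptide, made up 10.7% ± 5.09 of T cells in lucOS and 10.97% ± 2.63 in luc females (SD, n = 6 each, exact permutation p = 0.91). For TRBV12-1 alone the difference with lucOS was 2.94 points (exact permutation p = 0.135). Together, TRBV12-1 and TRBV12-2 made up 8.58% ± 1.94 with NICD and 13.1% ± 4.10 with sgp53 (SD, n = 6 each), a difference of -4.52 points by exact permutation (p = 0.02, adjusted p = 0.0625). The female NICD and sgp53 animals have numbers of separate series, so NICD and series cannot be told apart in any TCR measure. NICD animals lay between 5.96% and 11.69% and sgp53 animals between 9.926% and 20.41%. Within luc and within lucOS animals the difference was -2.87 and -6.17 points (n = 3 each, exact permutation p = 0.3 and 0.1). The highest was lucOS sgp53 replicate 2, where 1 TRBV12-1 clone held 127 of 169 such cells. Without it the difference was -3.06 points (exact permutation p = 0.025), and among distinct clonotypes it was -4.20 points (exact permutation p = 0.01). Without lucOS NICD replicates 3 and 2 in turn it was -4.29 and -3.99 points (exact permutation p = 0.055 and 0.06), and for TRBV12-1 alone -3.05 points (exact permutation p = 0.15). Of 20 TRBV entries 0 passed exact permutation with adjustment in either comparison. With 400 permutations the two-sided exact permutation p could not be under 0.005. TRBV13-2 and TRBV5 lay at that floor for lucOS and still had an adjusted p of 0.05, so this count is no sign of equal usage. The smallest p for lucOS against luc belonged to TRBV13-2 (-1.56 points), TRBV5 (-2.48 points) and TRBV12-2 (-3.19 points), with exact permutation p of 0.005, 0.005 and 0.01 and adjusted p of 0.05, 0.05 and 0.0667. With any 1 animal left out, their unadjusted exact permutation p was at most 0.025. Without lucOS NICD replicate 2, 3 entries passed. For NICD against sgp53 it belonged to TRBV14 (-4.06 points, exact permutation p = 0.01, adjusted p = 0.2), TRBV13-2 (0.964 points) and TRBV20 (0.732 points). Cells whose contig carried the joint entry TRBV12-2 and TRBV13-2 counted as an entry of their own, and counting them as TRBV13-2 turned its difference for lucOS to 11.08 points (exact permutation p = 0.035, adjusted p = 0.222). Of the 1406 cells of the joint entry 98.2% had a CDR3 that starts with CASG, as did all 84 cells of TRBV13-2 and 0 of 382 cells of TRBV12-2. The value of TRBV13-2 alone thus leaves out most such receptors, and its fall is no sign of lower use of that gene.

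Between NICD and sgp53 females the other measures had a larger p, and males were compared with only 2 animals. The expanded share was 25.9% ± 15.1 with NICD (SD, n = 4) and 27.6% ± 20.5 with sgp53 (SD, n = 6, exact permutation p = 0.838). These means mix the antigen constructs unequally, with 3 lucOS and 1 luc animal under NICD and 3 of each under sgp53. Within lucOS animals the difference was -10.11 points (n = 3 each, exact permutation p = 0.4), and within luc, with only 1 NICD animal, it was -6.219 points. The iNKT share was 2.53% ± 1.61 with NICD and 2.08% ± 1.16 with sgp53 (SD, n = 6 each, exact permutation p = 0.51). Male lucOS NICD animals (n = 2) had 43.5% ± 11.4 expanded cells against 32.3% ± 9.59 in females (n = 3), 3.33% ± 1.24 iNKT cells against 1.56% ± 0.935, and 8.89% ± 4.19 TRBV12 cells against 7.64% ± 1.77. Without male replicates 1 and 2 in turn, the difference was 3.08 and 19.27 points in the expanded share, 0.898 and 2.65 in the iNKT share, and 4.21 and -1.71 in the TRBV12 share. With 10 splits the exact permutation p cannot be under 0.1 there, and it was 0.4, 0.3 and 0.7.

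**Figure D4:**
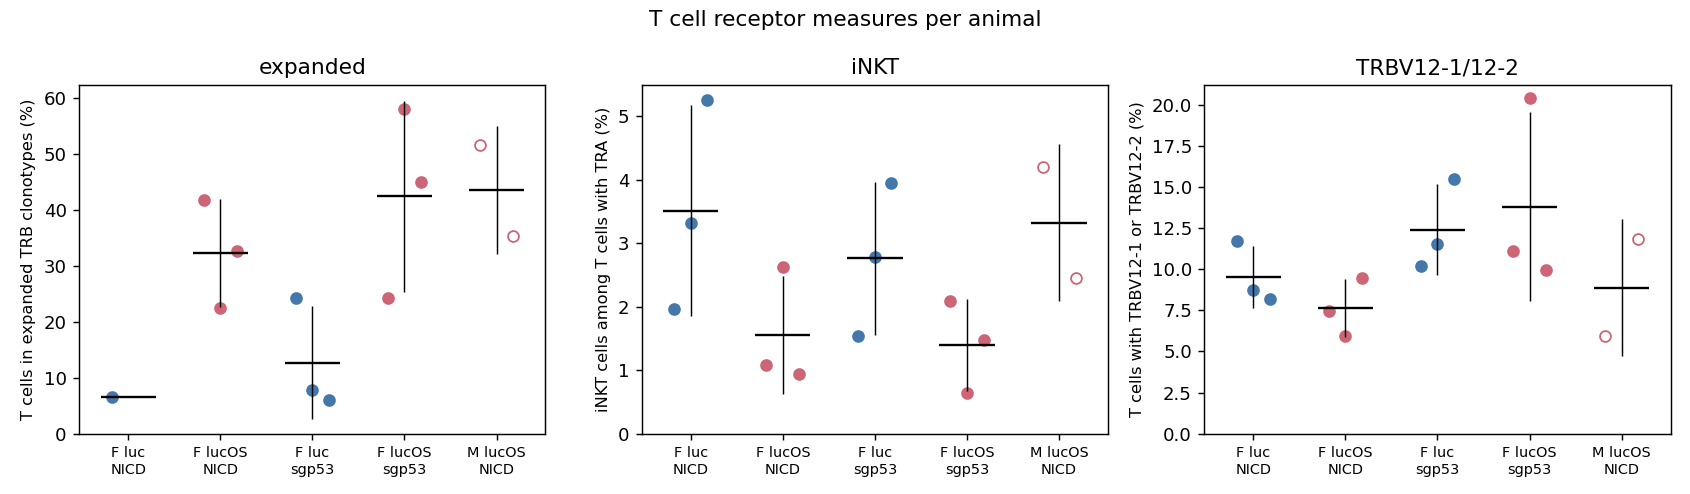
Share of T cells, in percent, in expanded TRB clonotypes after thinning, of iNKT cells among T cells with a TRA, and with TRBV12-1 or TRBV12-2, in 5 groups of animals. Each point is 1 animal (open for males), lines give the mean and bars the SD, 2 luc NICD animals under 100 T cells are missing from the expanded panel, and expanded shares run from 22.5% to 58.1% in lucOS females and from 6.03% to 24.3% in luc females.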

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

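The tests of other groupings of the libraries, of lung RNA, within animal number series, of the share of tumour cells and of identical nucleotide forms were chosen only after the result was seen. Among the genes fixed for naming, 58 groups of libraries were tested for a library far from the rest of its group, 8 had one, and chance gives about 2.9. Myc was 9.468 TPM in luc male replicate 1, where the other 3 lay between 15.8 and 16.9. Hes1, a NOTCH target, was 34.46 TPM in healthy replicate 4 (others 4.51 to 9.73), 150.5 in lucOS replicate 3 (others 39.2 to 66.5) and 67.03 in lucOS male replicate 4 (others 34.1 to 35.6). Sox9 was 2.303 TPM in healthy replicate 4 (others 0.840 to 1.15). Cd4 was 3.561 TPM in lucOS replicate 3 (others 0.699 to 1.14) and 1.837 in luc male replicate 4 (others 0.905 to 1.02). Foxp3 was 3.854 TPM in luc male replicate 3 (others 5.04 to 5.19).

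The antigen effect differed between male and other tumours for 6 gene lists by camera with a preset correlation. The median difference on the log2 scale was 1.37 for secreted hepatocyte proteins, 0.713 for macrophage markers, -0.615 for hypoxia genes, -0.466 for oncofetal genes, -0.423 for proliferation genes and -0.153 for MYC targets (adjusted p of 0.921 to 0.927 with an estimated correlation). The TCR libraries held 1009 productive contigs in barcodes not called cells, 5 to 160 per library.

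Other groupings of the same libraries were counted for each comparison of genes, the real one included. For tumours against healthy liver, 1 of 100 groupings called as many genes, the real one with 13986. The highest other called 10778, so chance can be excluded. No animal number series holds both healthy livers and tumours, so tumour and series cannot be told apart there. For males against other tumours, 1 of 100 did so in luc (2613, highest other 283) and 1 of 100 in lucOS (3778, highest other 1969), so chance can be excluded there. For lucOS against luc with no sex in the title, 46 of 100 groupings had as many genes as the real 385 at an unadjusted p under 0.05, with a highest other of 2190, so chance cannot be excluded. Within animal number series, with the series as a term, 36 of 100 reached the real 416, with a highest other of 2475, and one called 145 genes where the real one called 0, so a structure of the samples beyond antigen and series stays open, untested. For the interaction 13 of 100 reached the real 1842, with a highest other of 3156, so chance cannot be excluded. For lucOS against luc in males, 4 of 35 groupings called as many as the real 54, so chance cannot be excluded. The highest other called 860 genes, with luc male replicates 1, 3 and 4 and lucOS male replicate 3 against the rest, which is the real grouping with 1 pair exchanged. A structure of the samples other than the antigen was not tested and stays open.

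B cell genes were higher in male tumours of both constructs, Cd79a among them. If lung RNA had brought them, they would rise with Sftpc over the 8 male libraries, but the test decides nothing, with Spearman's rho = -0.238 (exact permutation p = 0.582) and Pearson's r = -0.129 (exact permutation p = 0.773), or 0.001 without the 2 libraries farthest out. A lower share of tumour cells would raise B cell and stellate cell genes alike. Their medians lay 1.147 apart in luc (permutation p = 0.0036, genes swapped between the lists) and 0.607 apart in lucOS (permutation p = 0.108). By the rule set, that spoke against this explanation in luc and left it open in lucOS. Genes are not independent replicates, though, and this p does not measure the spread between tumours, so the test cannot decide. The split by construct, and the bound of 0.5 within which medians would count as alike, were set after both values were seen, and an earlier wording would have favoured this explanation in lucOS. Sex and the animal series cannot be told apart, since all male tumours have animal numbers of 1 series and only their TPM sums depart from 1000000 (by up to 256.3), so a sex difference stays open and untested.

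TRB clonotypes were shared more often among lucOS than among luc females, with 26.03 more matches per 1000000 pairs (exact permutation p = 0.02, adjusted p = 0.0625). Sequences carried between libraries would be identical in nucleotides, and without the clonotypes that have an identical nucleotide form the difference was 14.68 (exact permutation p = 0.02), which argues against that as the whole cause. More T cells sampled in lucOS animals stays open, since after thinning to 151 T cells in 10 animals the difference was 106.8 (exact permutation p = 0.125). Higher use of the joint TRBV12-2 and TRBV13-2 entry stays open as well, with a difference of 15.48 without it (exact permutation p = 0.08). A response to the antigens of lucOS stays among the open explanations.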

How the results depend on the processing

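Tests chosen only after seeing the data were those without pseudogenes or microRNA genes, with the joint TRBV12-2 and TRBV13-2 entry counted, without iNKT cells for the expanded and TRBV12 shares, without libraries under 100 T cells or with all of them thinned to the smallest, and the gene lists with the animal number series as a term. Leaving out single healthy, luc and lucOS libraries, and any library for tumours against healthy liver, was added then too. Of the results that answer a comparison, 138 of 158 under other settings and 169 of 205 with 1 library left out counted as the same. For TCR shares and sharing, that meant the same direction and the same side of an unadjusted p of 0.05. For counts of genes, gene lists or TRBV entries, it meant an equal count or one within a factor of 1.5. Whether a count kept its split into higher and lower was not judged. Of the values of single genes, 1889 of 1971 and 2291 of 2474 kept their direction and their side of the adjusted threshold. All 36 named genes called between tumours and healthy liver kept their call. The cause was not tested where a value moved, except that fewer samples leave fewer permutations. Tests on read counts were not run, since whole reads cannot be recovered from TPM, and the unknown depth limits genes of low TPM. With the animal number series as a term, lucOS against luc with no sex in the title called 0 genes and 9 gene lists, the same 9 as without it (adjusted p of 0.79 to 0.87 with an estimated correlation). Without barcodes that may be doublets the expanded, iNKT and TRBV12 shares kept their direction and side.

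With an estimated correlation the gene lists called numbered 1 for tumours against healthy liver, 0 and 0 for lucOS against luc (sex not in title, males), 1 and 1 for males (luc, lucOS) and 0 for the interaction. The count for lucOS against luc in males was 34 with no low-value filter and 0 with only its groups in the fit, and that of the interaction was 4 with all 26 libraries. Directions turned for uncalled genes: Afp with pseudocount 5 (0.0031), Cd4 in luc males with quantile normalization (-0.0439), and with array weights Myc for lucOS with no sex in the title (-0.0425), in males (0.1952) and in the interaction (0.2377). Foxp3 in the interaction was -0.105 with quantile normalization, -0.0428 with median ratio scaling and -0.0615 with array weights.

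The expanded share of NICD against sgp53 was 1.716 with paired TRA and TRB and 0.4655 by entropy, and that of males against females was -0.6892 by entropy. Values of the expanded share for NICD mix luc and lucOS animals unequally, so a turned direction there can come from that mix. The iNKT share was -0.9116 for lucOS and -0.1769 for NICD with at least 3 UMIs, and -1.423 and -0.08608 with libraries under 100 T cells left out. The TRBV12 share was 2.94 for lucOS and -3.047 for NICD with TRBV12-1 alone, and 12.39 and -9.195 with the joint entry counted. Counting that entry as TRBV12 is doubtful, since 98.2% of its cells have a CDR3 that starts with CASG, and 0 of the 382 TRBV12-2 cells do. TRBV13-2 was 11.08 for lucOS and -3.713 for NICD with that entry, and TRBV20 was -0.1145 for NICD among distinct clonotypes. Without both libraries of lucOS sgp53 replicate 3, the expanded share was 24.69 for lucOS and 1.759 for NICD, and the iNKT share -1.659 for lucOS.

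With 1 library left out, genes called ranged from 0 to 1 (lucOS against luc, sex not in title), 0 to 578 (males), 1488 to 3045 (males against others, luc), 1863 to 4792 (lucOS) and 0 to 1 (interaction). The expanded share ranged from 22.06 to 30.58 (lucOS) and -6.986 to 4.742 (NICD). That 4.742 was without luc NICD replicate 1, the only luc animal with NICD in this measure. The iNKT share ranged from -1.978 to -1.235 (lucOS) and -0.09304 to 0.8273 (NICD), and the TRBV12 share from -2.183 to 0.7074 (lucOS), -5.154 to -3.057 (NICD; -5.139 without luc NICD replicate 2) and -1.713 to 4.21 (males). Sharing ranged from 21.91 to 33.27 (23.42 without lucOS sgp53 replicate 2) and V genes called for lucOS from 0 to 3. Myc ranged from -0.0519 to 0.1038 (lucOS, sex not in title) and -0.313 to 0.0338 (lucOS, males), Cd4 from -0.0372 to 0.2847 (lucOS, sex not in title) and -0.0232 to 0.2266 (luc males), and Cxcl9 from -0.0483 to 0.333 (luc males). Notch1 ranged from -0.0552 to 0.4145 (lucOS, males) and -0.3549 to 0.1148 (interaction), B2m from -0.1453 to 0.4852 and -0.4863 to 0.1442 in the same order, Cd274 from -0.133 to 0.3368 and Foxp3 from -0.0465 to 0.0832 (interaction), and Sox9 from -0.4432 to 0.195 (lucOS males).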

Other observations

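The tests of the glycine pattern were chosen only after the result was seen, and the fit that averages the antigen effect was added after the data were seen. Averaged over tumours with and without a male label, interferon gamma genes (14 of 14 positive, median 0.63), MHC class II genes (10 of 10, 0.79) and cytotoxic effector genes (8 of 8, 0.49) lay higher with lucOS. These 3 lists passed camera, with adjusted p = 0.726 with an estimated correlation, and adjusted over the list alone 3, 3 and 0 of their genes were higher. They were not the only lists to pass. The smallest camera adjusted p, 8.5e-09, was that of the respiratory chain (14 of 14 positive, median 0.237). Type I interferon and p53 target genes passed as higher too, and hypoxia and monocyte and neutrophil genes as lower. With an estimated correlation all these had adjusted p of 0.726 to 0.905. Limma called 3 of 15453 genes in this average, with 1814 at an unadjusted p under 0.05. Snai1, a transcription factor of the epithelial to mesenchymal transition, was lower with lucOS (log2 fold change -0.96 ± 0.15, SE), and Rabggtb (0.32 ± 0.05) and Krt222 (0.78 ± 0.13) were higher. The value of Krt222 comes mostly from males, with 1.44 there and 0.11 in tumours with no sex in the title (interaction adjusted p = 0.239). They were named for being the only genes called. The count was 16 without luc replicate 3, 10 without luc male replicate 4, 2 without lucOS male replicate 4, 1 without luc male replicate 2 or lucOS male replicate 3, and 0 without any 1 of the other libraries except luc male replicate 1, where it was 3.

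An antigen effect common to both kinds of tumour may lie behind the interferon gamma, MHC class II and cytotoxic lists, and a test asked whether the average calls any of their genes. The members of the 3 lists called higher in the average over both kinds of tumour numbered 0, an outcome first written down as speaking against an antigen effect common to tumours with and without a male label. That was wrong, because missing the threshold excludes nothing while every gene of the 3 lists is positive, so the question stays open.

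Among T cells, the joint entry TRBV12-2 and TRBV13-2 made up 21.1% ± 9.38 in lucOS and 8.42% ± 3.95 in luc females (SD, n = 6 each, exact permutation p = 0.03, adjusted p = 0.15). Of its 1406 cells 98.2% had a CDR3 that starts with CASG, as did all 84 cells of TRBV13-2 and 0 of the 382 cells of TRBV12-2. The CDR3s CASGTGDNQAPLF and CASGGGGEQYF of this entry were each found in 4 lucOS animals and no luc animal, in 3 and 4 nucleotide forms. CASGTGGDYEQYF (74 cells) was found in 4 lucOS animals as well, a male among them, in 1 nucleotide form, as sequences carried between libraries would be. These 3 were chosen after their values were seen.

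A candidate explanation is that clones raised by the lucOS antigens carry glycine at the third place after CAS in such receptors. They made up 13.6% ± 8.89 of T cells in lucOS and 2.07% ± 1.80 in luc females (SD, n = 6 each), which is 11.49 points more (exact permutation p = 0.015). The groups overlap, with 2.184% in lucOS sgp53 replicate 1 and up to 4.545% in luc animals, and male lucOS NICD replicate 2 had 3.002%. Among distinct clonotypes the difference was 2.61 points (exact permutation p = 0.055), and such receptors without the glycine differed by -0.410 points (exact permutation p = 0.695). The pattern was found in these same libraries, so the hypothesis stays open.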
